A study of Arabidopsis thaliana with 12 samples.

How the data were processed

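RNA of whole Arabidopsis seedlings was measured on 12 one-colour Agilent arrays: wild type (Col-0) and the SvGRP transformant, each at 0 and 150 mM NaCl for 24 h, with 3 arrays per group. Per the labels, RNA was extracted with an RNeasy Plant kit, labelled with Cy3 by linear amplification and read with Agilent Feature Extraction, whose version is not given in the sources used here. The labels number the replicates 1 to 3 and do not say whether these were grown separately. The p-values measure only the spread between these samples, which may be technical.

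The deposited array files give an intensity for each probe, the processed signal of the scanner software on a linear scale, not scaled between arrays and without spot flags, background or mean signal columns. The authors' deposited series table holds log2 values: each equalled log2 of the signal minus the array's 75th percentile, centred on the probe's median over the 12 arrays, with a largest absolute difference of 0.000389. The intensities were used, and the log2 table served as an alternative.

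Each array file held 43663 values, of which 60 were controls. Of the 43603 other probes, 34344 were listed with 1 gene in the probe table and 9259 were not listed. Names came from a RefSeq gene table (assembly TAIR10.1, used only for names): 32283 probes matched by accession, 1318 by locus tag and 698 by symbol, and 45 kept the name in the probe table. They named 24716 genes, 7315 of them with more than 1 probe. The log2 intensity minus the array's 75th percentile was analysed. The files carry no flags, so a probe was kept when its signal was above the array's 20th percentile on all arrays of at least 1 group, and 35454 probes passed. The probe with the highest mean stood for its gene, which left 26794 genes or unnamed probes to test, 20917 of them with a gene name. A gene below that percentile on all arrays of a group is given as at least N-fold higher or lower against it.

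limma 3.58.1 in R 4.3.3 fitted a mean per group, and moderated tests (8 residual and 1.74 prior degrees of freedom) compared salt with control in each genotype, SvGRP with wild type at each NaCl level, and the salt responses of the genotypes (the interaction). A gene is called at a Benjamini-Hochberg adjusted p under 0.05. Slide was also fitted as a fixed term, which left 6 residual degrees of freedom. Limma's camera with a preset correlation of 0.01 compared each of 28 gene lists with all other genes, and the p-values of all 140 list tests were adjusted together; of 448 list members 407 were measured. The comparisons, the lists, the alternatives other than the median and E1A scalings, and the rule for named genes were fixed before the data were examined. That rule takes, for each comparison, the 8 largest rises and falls among called genes with a symbol whose groups do not overlap, up to 2 called members of each list in either direction, and always RD29A, RD29B, RAB18, P5CS1, NCED3, SOS1, HKT1, GRP7 and GRP8; some list members are given as counts only.

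Means of gene sets per array were compared by linear models with 95% t intervals, and the interval of a set's distance from a response larger by the LEA list's factor came from the delta method. The code was tested on simulated data for SvGRP at 0 mM with 26794 genes. Without slide effects, 88% of 2-fold and 93% of 4-fold changes were recovered with 10 unchanged genes called, and with slide in the fit 51% and 78% with 11. With a slide effect of SD 0.3 (log2), the fit without slide called 3821 unchanged genes and the fit with slide 4, with 46% and 75% recovered. Of simulated lists, 0 of 100 unchanged and 20 of 20 raised by 1 (log2) were called. The simulated genes varied independently, so this says nothing of false list calls among genes that vary together.

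Alternatives were quantile normalization, the series table, no or a strict filter on dim probes, slide as a fixed or random block, the replicate number as a block, leaving out each array, a 2-fold threshold, a fit of only the groups compared, all probes, a trended robust variance, an estimated correlation for lists, and scaling to the array's median or to 8 E1A spike-in probes, these last chosen after seeing the data. A background correction from mean and background signals was not run, because those columns are not held.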

Results

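Gene expression was measured in whole seedlings of Arabidopsis thaliana on 12 one-colour arrays, 3 in each of 4 groups. The wild type (Col-0) was set beside a transformant, called SvGRP here, that carries a gene for a glycine-rich RNA-binding protein of the salt-tolerant grass Sporobolus virginicus. Seedlings of both genotypes were moved at 5 days to plates with 0 or 150 mM NaCl and harvested 24 h later. The series asks how the transformant and the wild type differ in gene expression under salt stress. Median signal per array ran from 676 to 1013, the 75th percentile from 3641 to 5676 and the 20th percentile from 14.1 to 27.6, and the number of arrays limits the precision. The array design was not checked for the SvGRP transgene, which is not analysed here. Arrays of a group correlated with r between 0.990 and 0.997 across genes, and the median SD of a gene was 0.09 and 0.10 (log2) in wild type at 0 and 150 mM and 0.06 and 0.13 in SvGRP. Principal component 1 held 68.6% of the variance and parted the arrays by NaCl, and component 2 held 12.8% and parted them by genotype.

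**Figure D1:**
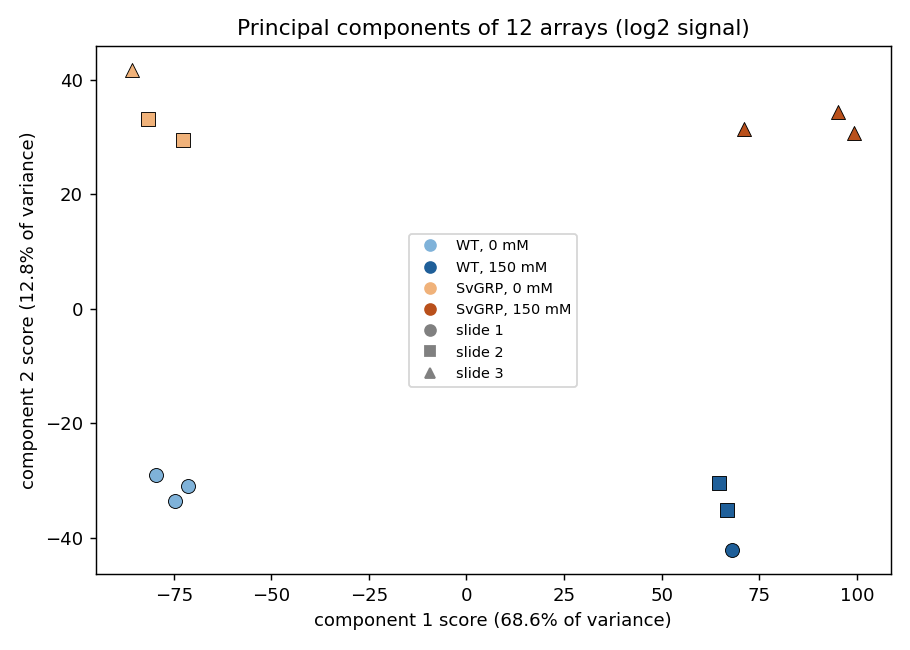
Scores of the 12 arrays on the first principal components of the log2 values; colour gives the group and shape the slide. The 0 mM arrays lie between -85.7 and -71.3 on component 1 and the 150 mM arrays between 64.7 and 99.4, while wild type lies below 0 and SvGRP above 0 on component 2.

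The arrays came from 3 slides of 4 arrays. Slide 1 held the 3 wild-type arrays at 0 mM and wild type at 150 mM replicate 1. Slide 2 held the other wild-type arrays at 150 mM and SvGRP at 0 mM replicates 1 and 2, and slide 3 held the remaining SvGRP arrays. Component 3, with 7.49% of the variance, set slide 2 apart within groups. Wild type at 150 mM lay at -36.1 and -35.4 on slide 2 and at -3.18 on slide 1. SvGRP at 0 mM lay at -28.2 and -33.5 on slide 2 and at -4.93 on slide 3. The other groups lay at 15.8 to 31.0, so this component mixes slide with the contrast of the interaction. No slide held both genotypes at the same NaCl level. A value in parentheses after a result is therefore the value with slide in the fit, which for the salt comparisons is the value within slide 1 (wild type) or within slide 3 (SvGRP). Slide 1 held 1 wild-type array at 150 mM (replicate 1), and slide 3 held 1 SvGRP array at 0 mM (replicate 3). With slide in the fit, salt in wild type and SvGRP at 0 mM rest on the first of these arrays. Salt in SvGRP and SvGRP at 150 mM rest on the second, and the interaction rests on both. Values after ± are standard errors, with n = 3 arrays per group. All changes are relative to the 75th percentile of the array. When the arrays were scaled to the 8 E1A spike-in probes instead, the median of all genes lay at 0.46 for salt in wild type, 0.16 for salt in SvGRP, 0.39 for SvGRP at 0 mM, 0.14 for SvGRP at 150 mM and -0.24 for the interaction.

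Salt in wild type was compared first. Genes of the response to abscisic acid (ABA), the hormone of water deficit, rose: RD29A (AT5G52310) by 1.66 ± 0.23 (log2, adjusted p = 1.8e-04, 1.88 within slide 1), RD29B (AT5G52300) by 3.19 ± 0.57 (adjusted p = 7.8e-04, 3.77) and the dehydrin gene RAB18 (AT5G66400) by 2.61 ± 0.23 (adjusted p = 1.2e-05, 2.84). NCED3 (AT3G14440), whose product makes the ABA precursor, rose by 2.25 ± 0.28 (2.05 within slide 1) and P5CS1 (AT2G39800), for proline synthesis, by 0.95 ± 0.19 (1.31). HKT1 (AT4G10310), which withdraws sodium from the xylem, fell by 3.11 ± 0.16 (-2.89 within slide 1), whereas the sodium exporter gene SOS1 (AT2G01980) had a log2 fold change of 0.03 ± 0.05 (adjusted p = 0.65, 0.06), or 0.46 and adjusted p = 0.0017 under E1A scaling. Among the largest rises, the transcription factor gene BHLH92 (AT5G43650) was at least 231-fold higher, with a fitted change of 9.09 (9.26 within slide 1). Among the largest falls, the anion channel homologue SLAH1 (AT1G62280) was at least 35.5-fold lower (fitted -5.92, -6.15) and the iron transporter IRT1 (AT4G19690) at least 23.5-fold lower (fitted -5.49, -5.64).

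Of the 26 measured genes for LEA proteins, dehydrins and other ABA or osmotic stress products, 19 rose and 1, COR15B (-1.24, -1.03 within slide 1), fell; EM1 rose by 6.68 (6.31) and LTP4 by 6.69 (6.93). The list's median was 1.22 (1.31 within slide 1, adjusted p = 4.3e-04, and adjusted p = 0.58 with an estimated correlation). Of the 9 clade A protein phosphatases 2C, which damp ABA signalling, 8 rose, HAI2 by 4.45 ± 0.46, with a median of 1.02 (1.00, adjusted p = 0.014, 0.073 under E1A scaling, and adjusted p = 0.58 with an estimated correlation). Of the 9 ABA receptor genes, 7 fell, PYL6 by 2.99 ± 0.24, and 1 rose, with a median of -0.46 (-0.56, -0.035 under E1A scaling, adjusted p = 0.030, and adjusted p = 0.58 with an estimated correlation). Of 19 heat shock genes, 17 rose and 18 passed adjusted over the list alone. Their median was 2.201 (2.21, adjusted p = 1.7e-06, and adjusted p = 0.58 with an estimated correlation), and HSP23.6, a mitochondrial small heat shock protein gene, was at least 106-fold higher. In the flavonoid and anthocyanin list, 13 of 19 genes rose, DFR by 5.79 ± 0.20 and UF3GT by 5.37 ± 0.14, and 2 fell. Its median was 2.101 (1.296 within slide 1, adjusted p = 2.4e-04, and adjusted p = 0.58 with an estimated correlation), or 1.02 with 2 members set to their bounds and 0.83 with genes above the dim-probe threshold on all 12 arrays. Of 20 jasmonate genes, 18 rose, the repressor genes JAZ8 by 4.85 (7.17) and JAZ7 by 3.97 (5.80), and 2 fell, among them PDF1.2 (not called within slide 1). That list's median was 1.61 (1.93, adjusted p = 3.7e-04, and adjusted p = 0.58 with an estimated correlation).

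Photosynthesis genes fell together: 33 of 34 fell and none rose, among them PRK by 1.15 ± 0.13 and RCA by 0.96 ± 0.07, with a median of -0.68 (-0.64 within slide 1, adjusted p = 6.0e-11, and adjusted p = 0.58 with an estimated correlation). All 11 measured aquaporin genes fell, PIP1A by 1.39 ± 0.08 and PIP2B by 1.26 ± 0.08, with a median of -0.89 (-0.75, adjusted p = 1.1e-05, and adjusted p = 0.58 with an estimated correlation). In the nitrate uptake and nitrogen assimilation list, 9 of 12 genes fell, NRT1.5 by 3.23 ± 0.18 and ASN1 by 2.82 ± 0.21, and 2 rose, including NRT2.1 (1.46 ± 0.22). Its median was -0.76 (-0.73, adjusted p = 0.0017, and adjusted p = 0.58 with an estimated correlation). Of 11 markers of the shoot apex, leaf and stomatal lineage, 8 fell, FIL by 1.04 and SPCH by 1.01, with a median of -0.51 (-0.57, adjusted p = 0.025, and adjusted p = 0.58 with an estimated correlation). That call ended without wild type at 150 mM replicate 2 (adjusted p = 0.051) and with slide in the fit (adjusted p = 0.059). Under E1A scaling the medians were -0.25 for photosynthesis, -0.46 for aquaporins, -0.33 for the nitrogen list and -0.078 for the shoot markers, and under quantile normalization the first 2 were -0.13 and -0.50.

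The other 18 lists were not called for salt in wild type. The glycine-rich list was called under quantile normalization (adjusted p = 0.035) and the ethylene list with no filter on dim probes (0.034). In the sodium, potassium and proton transport list, 7 of 21 genes rose, CAX3 by 2.37 (2.63), and 10 fell, and the potassium channel gene SKOR fell by 3.65 (-3.62). The ethylene list had 10 rises, ACS2 by 4.72 and ACS7 by 4.097, and 3 falls among 19 genes (median 0.38, adjusted p = 0.11). The salicylate and pathogen list had 8 rises and 7 falls among 19 genes (adjusted p = 0.97), where WRKY54 fell by 2.90 (-2.98) and WRKY70 fell by 2.33 (-2.23). Rises and falls numbered 7 and 2 of 11 for ABA synthesis and catabolism, 3 and 0 of 9 for ABA kinases and transcription factors, 5 and 2 of 10 for proline metabolism, 2 and 2 of 7 for galactinol and raffinose synthesis, and 10 and 7 of 23 for reactive oxygen scavenging. They numbered 7 and 4 of 12 for glycine-rich RNA-binding and cold shock domain proteins, 2 and 5 of 14 for aliphatic glucosinolate synthesis, 6 and 2 of 12 for indole glucosinolates and myrosinases, 6 and 8 of 22 for expansins and xyloglucan endotransglucosylases, and 1 and 7 of 12 for the circadian clock. Cell division gave 0 and 4 of 9, senescence 5 and 2 of 10, the root and root-hair markers 3 and 2 of 13, the seed storage markers 2 and 2 of 7, and the reference genes 0 and 3 of 7, with a median of -0.04. Under E1A scaling the medians turned from -0.25 to 0.18 for aliphatic glucosinolates, from -0.26 to 0.17 for the clock, from -0.16 to 0.26 for cell division and to 0.39 for the reference genes. Median, mean and test differed in sign for 5 of these lists: the salicylate list (0.08, 0.35 and down), sodium transport (0.03, -0.33 and down), galactinol synthesis (-0.03, 0.54 and up), expansins (-0.06, 0.07 and down) and the root markers (0.40, -0.27 and up). The ABA synthesis median was 0.71, or 0.51 with 1 member at its bound. GRP7 (AT2G21660) and GRP8 (AT4G39260), the clock-controlled Arabidopsis relatives of the transgene's product, fell by 0.31 ± 0.08 and 0.40 ± 0.12 (-0.27 and -0.39 within slide 1, not called there). Both turned to 0.17 and 0.08 under quantile normalization and to 0.11 and 0.02 under E1A scaling. The 75th percentile was 3641 to 4226 on wild-type arrays at 0 mM and 4946 to 5198 at 150 mM. The unscaled signal of GRP7 did not fall, so its fall is one relative to that percentile. GRP7 is a bright gene, 6.81 to 7.12 (log2) above that percentile at 0 mM. Whether its probe was saturated was not tested, so the unscaled signal cannot settle whether its RNA fell.

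In all, limma called 16947 of 26794 genes for salt in wild type, 8865 higher and 8082 lower, of which 3985 changed at least 2-fold. A fit with slide called 12257, and 11814 of these were called in the same direction without it. Under E1A scaling 86.0% of the calls were higher, against 52.3% in the fit described here.

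Salt in SvGRP gave the same question in the transformant. RD29A rose by 2.89 ± 0.23 (adjusted p = 3.8e-06, 3.19 within slide 3), RD29B by 5.41 ± 0.57 (6.06), RAB18 by 2.84 ± 0.23 (2.86), NCED3 by 2.88 ± 0.28 (3.17) and P5CS1 by 1.67 ± 0.19 (1.86). LTP4, a lipid transfer protein gene, was among the largest rises, at 10.52 ± 0.68 (11.98). HKT1 fell by 3.18 ± 0.16 (-3.17), IRT1 was at least 39.5-fold lower (fitted -6.82, -7.31) and SLAH1 at least 66.2-fold lower (fitted -6.73, -6.95). SOS1 rose by 0.18 ± 0.05 (adjusted p = 0.013, 0.14 and not called with slide in the fit), a call that ended without SvGRP at 0 mM replicate 2 (adjusted p = 0.057). GRP7 had a change of -0.05 ± 0.08 (adjusted p = 0.57, 0.05, and 0.29 with adjusted p = 0.0064 under quantile normalization), and GRP8 fell by 0.33 ± 0.12 (adjusted p = 0.028, -0.18 and not called with slide in the fit). The call of GRP8 ended without any 1 of 4 arrays (highest adjusted p = 0.10, without SvGRP at 150 mM replicate 2). It ended also under quantile normalization (-0.084, adjusted p = 0.54) and under E1A scaling (-0.11, adjusted p = 0.47).

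Of the LEA and dehydrin list, 23 of 26 genes rose and 1 fell, with a median of 2.201 (2.32 within slide 3, adjusted p = 8.4e-08), and all 9 clade A phosphatase genes rose, HAI2 by 5.60, with a median of 1.76 (1.86, adjusted p = 8.4e-04). Of 19 heat shock genes 18 rose (median 3.57, 3.72 within slide 3, adjusted p = 4.1e-08). Of 19 flavonoid genes 15 rose, PAP1 by 4.62 (4.75) and TT19 by 4.29 (4.12), and 2 fell (median 2.76, 2.87 within slide 3, adjusted p = 2.7e-05, 1.88 with 2 members at their bounds, and 1.23 with genes above the dim-probe threshold on all 12 arrays). Of 20 jasmonate genes 13 rose and 0 fell (median 1.16, 1.40 within slide 3, adjusted p = 0.0049). Of 34 photosynthesis genes 32 fell (median -0.51, -0.49 within slide 3, -0.17 under quantile normalization, -0.28 under E1A scaling, adjusted p = 1.2e-05), and of 11 aquaporin genes 10 fell (median -1.05, -1.02 within slide 3, adjusted p = 3.0e-04). Of 12 nitrogen genes 10 fell and 2 rose (median -0.85, -0.90 within slide 3, adjusted p = 0.0050); NIA1 fell by 3.25 (-3.33) and NRT1.5 fell by 3.78 (-3.98). Of 9 ABA receptor genes 8 fell and 1 rose (median -0.80, -0.74 within slide 3, adjusted p = 0.022). Of 14 aliphatic glucosinolate genes 12 fell and 1 rose (median -1.08, -1.03 within slide 3, adjusted p = 0.0085); MAM3 fell by 2.49 (-2.31) and BCAT4 fell by 2.25 (-2.12). Of 22 expansin and xyloglucan endotransglucosylase genes 12 fell and 1 rose (median -0.68, adjusted p = 0.036), with -0.40 and adjusted p = 0.11 with slide in the fit and -0.45 under E1A scaling. Among them EXPA8 fell by 3.00 (-3.07) and XTH17 fell by 1.78 (-1.70). Of 12 glycine-rich RNA-binding and cold shock domain genes 8 rose, GR-RBP3 by 1.53 and GR-RBP2 by 1.05, and 3 fell (median 0.42, 0.43, 0.64 under E1A scaling, adjusted p = 0.037, and 0.057 without SvGRP at 150 mM replicate 3). The ABA kinase and transcription factor list (5 of 9 rose, ABI5 by 1.32 and ABF2 by 1.23, median 0.26, 0.39) had an adjusted p of 0.044. It was 0.070 without SvGRP at 0 mM replicate 3 and 0.065 without SvGRP at 150 mM replicate 2, 0.052 without SvGRP at 150 mM replicate 3 (median 0.16), and 0.055 under E1A scaling (median 0.48). The ABA synthesis and catabolism list (8 of 11 rose, 2 fell, median 1.01, 1.03) had an adjusted p of 0.048. That call ended with slide in the fit (0.062), under quantile normalization (0.067), under E1A scaling (0.055) and without any 1 of 6 arrays, with the highest adjusted p, 0.071, without wild type at 150 mM replicate 3. For these 14 lists the adjusted p with an estimated correlation was between 0.58 and 0.60, so none was called that way.

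In SvGRP 18442 genes were called, 8315 higher and 10127 lower, of which 5367 changed at least 2-fold. A fit with slide called 14505, 14270 of them in the same direction as without it. Under E1A scaling 64.7% of the calls were higher, against 45.1%. Of the genes called in both genotypes, 6850 were higher in both (2751 expected for independent lists), 7104 were lower in both (3055 expected) and 280 went opposite ways. The last count was 615 without wild type at 150 mM replicate 1, 172 and 186 without replicates 2 and 3 of that group, 167 and 159 without SvGRP at 0 mM replicates 1 and 2. It was 67 with slide in the fit. Under E1A scaling 2469 genes were lower in both. The salt comparisons share no array, and across genes, which are not independent replicates, their changes correlated with r = 0.826 and rho = 0.773. Calls in wild type alone numbered 2713 and in SvGRP alone 4208. Whether such a gene's response differs is tested by the interaction, given last.

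SvGRP was compared with wild type at 0 mM to find differences present without salt. GRP7 fell by 1.58 ± 0.08 (adjusted p = 4.3e-06, -1.47 with slide in the fit, adjusted p = 0.0089) and GRP8 by 1.07 ± 0.12 (adjusted p = 4.6e-04, -0.97, adjusted p = 0.10). ELF4 (AT2G40080) and LUX (AT3G46640), of the evening complex of the circadian clock, fell by 2.12 ± 0.09 (-2.30) and 1.62 ± 0.11 (-1.59), and the cold- and clock-regulated COR27 (AT5G42900) by 4.31 ± 0.10 (adjusted p = 4.5e-08, -4.25). The morning genes CCA1 and LHY rose by 0.64 ± 0.07 (0.51, adjusted p = 0.15 with slide in the fit) and 0.62 ± 0.10 (0.35, adjusted p = 0.40). Among genes of salicylate responses, WRKY70 (AT3G56400) fell by 3.60 ± 0.11 (-3.37), NIMIN1 (AT1G02450) by 3.40 ± 0.29 (-3.50) and the pathogen- and clock-regulated PCC1 (AT3G22231) fell by 9.56 ± 0.88 (-10.04, adjusted p = 0.053), while 13 of the 19 genes of the fixed list were not called.

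**Figure D2:**
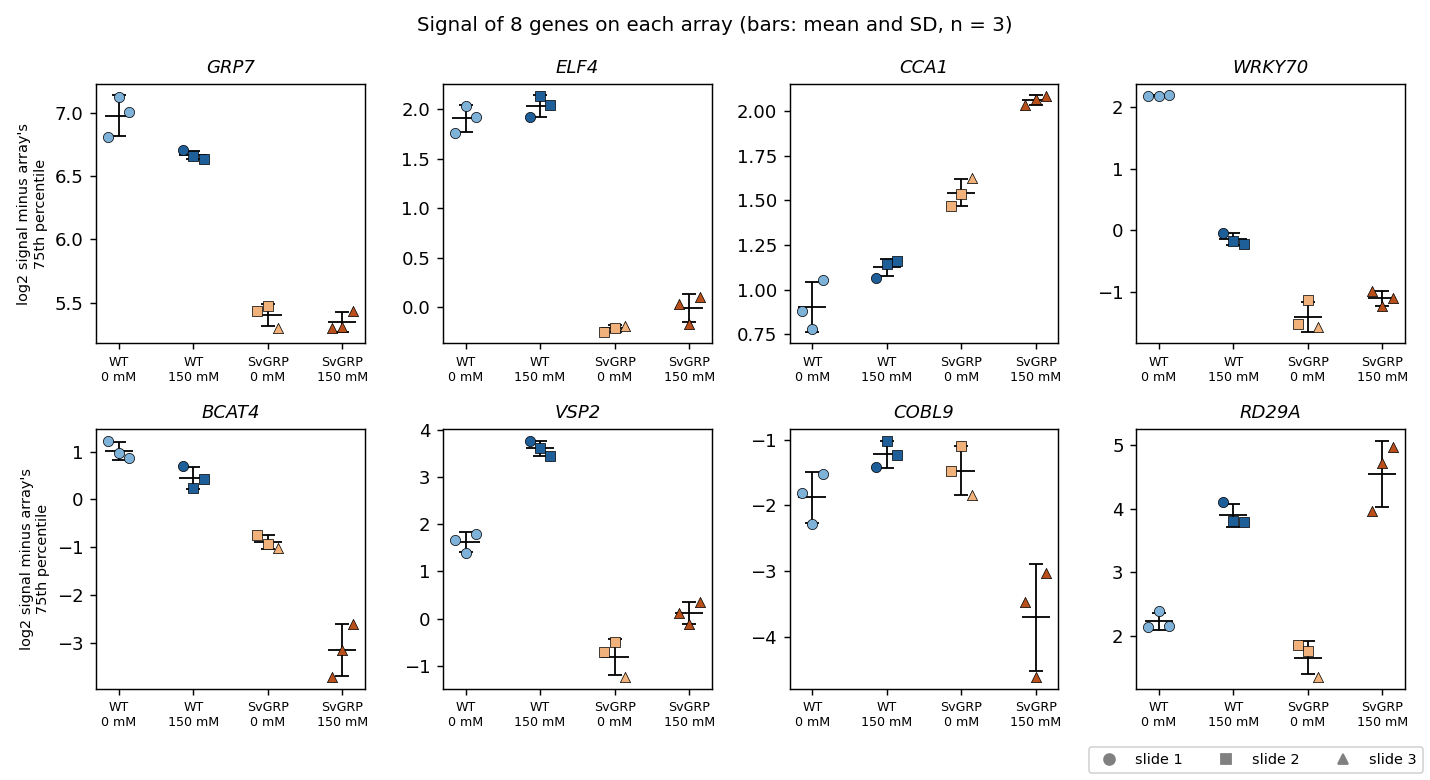
Log2 signal minus the array's 75th percentile for 8 genes on each of the 12 arrays; shape gives the slide, bars the group mean and SD (n = 3). GRP7, ELF4 and WRKY70 lie lower in SvGRP than in wild type at 0 mM on every array, CCA1 lies higher, and RD29A lies higher at 150 mM than at 0 mM in both genotypes.

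Of 14 aliphatic glucosinolate genes 12 fell and none rose (13 fell adjusted over the list alone), with a median of -0.82 (-0.58 with slide in the fit, -0.46 under E1A scaling, adjusted p = 2.6e-08, and adjusted p = 0.58 with an estimated correlation). Among them were CYP79F1 (-2.14 ± 0.51, -1.82, not called with slide in the fit) and BCAT4 (-1.91 ± 0.24, -1.49, likewise). The myrosinase gene TGG2 fell by 1.41 ± 0.08 (-1.41). In the jasmonate list 7 of 20 genes fell, VSP2, a vegetative storage protein gene, by 2.43 ± 0.20 (-1.97), with a median of -0.39 (adjusted p = 0.0011, and adjusted p = 0.58 with an estimated correlation). That median turned to 0.16 with slide in the fit (adjusted p = 0.31) and was -0.027 under E1A scaling. In the salicylate list 6 of 19 fell (median -0.41, -0.25 and adjusted p = 0.18 with slide in the fit, -0.050 under E1A scaling, -0.66 without wild type at 0 mM replicate 2, adjusted p = 0.0043, and adjusted p = 0.58 with an estimated correlation). Of the 12 glycine-rich RNA-binding and cold shock domain genes 5 fell (median -0.16, -0.18, adjusted p = 0.0043, and adjusted p = 0.58 with an estimated correlation, the median was 0.20 under E1A scaling). Of 34 photosynthesis genes 14 fell, PSBO1 by 0.40 (-0.29, not called with slide in the fit, and -0.04 and not called under E1A scaling), and 1 rose (18 and 1 adjusted over the list alone). Their median was -0.22 (-0.16, adjusted p = 0.073 with slide in the fit, adjusted p = 1.2e-05, and adjusted p = 0.59 with an estimated correlation), and it turned to 0.03 under quantile normalization and 0.14 under E1A scaling. Of the LEA and dehydrin list 6 of 26 fell, LTP4 by 3.28 (-2.18, adjusted p = 0.38 with slide in the fit) and COR15B by 1.28 (-0.95, 0.27). The list had a median of -0.34 (0.06 and adjusted p = 0.57 with slide in the fit, 0.02 under E1A scaling, adjusted p = 0.0030, and adjusted p = 0.63 with an estimated correlation). It was -0.205 without wild type at 0 mM replicate 3 and -0.19 without SvGRP at 0 mM replicate 3. Of 19 heat shock genes 6 fell, HSP90.1 by 1.31 (-1.40, not called with slide in the fit), with a median of -0.29 (-0.59, 0.07 under E1A scaling, adjusted p = 0.0070, and adjusted p = 0.59 with an estimated correlation). That median was -0.44 without wild type at 0 mM replicate 2, -0.15 without SvGRP at 0 mM replicate 3 and -0.72 with genes above the dim-probe threshold on all 12 arrays. Members of the flavonoid list went both ways, LDOX and DFR rising by 1.47 and 1.18 (1.16 and 1.00) and FLS1 and TT7 falling by 1.47 and 1.28 (-1.65 and -1.91), none of the 4 called with slide in the fit. The list had 6 rises and 4 falls among 19 genes (adjusted p = 0.83). RD29A had a change of -0.57 ± 0.23 (adjusted p = 0.11, -0.11), RD29B of -0.35 (0.85), RAB18 of -0.06, P5CS1 of 0.10, NCED3 of 0.16, SOS1 of -0.10 and HKT1 of 0.49 ± 0.16 (adjusted p = 0.054), none called. Under E1A scaling SOS1 turned to 0.26 (adjusted p = 0.040) and HKT1 was at 0.85 (0.0018), both called.

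Among the largest falls, CYP93D1 was at least 9.35-fold lower (fitted -6.49, -4.84 with slide in the fit), the ankyrin-repeat gene ANK at least 19.4-fold lower (fitted -6.27, -6.19, not called with slide in the fit) and the zinc transporter family gene ZIP7 at least 2.15-fold lower (fitted -4.22, -4.70). SIB1 fell by 3.93 (-4.36) and the potassium uptake gene HAK5 by 3.67 ± 0.25 (-3.64). The largest rise measured on all 6 arrays was that of the LOB-domain gene LBD20, by 3.63 ± 0.26 (2.70). The seed storage and oil body markers, fixed as signs of ungerminated seed, rose in 4 of 7 genes, OLEO2 by 1.77 ± 0.34 (2.29, not called with slide in the fit), and fell in 1, with a median of 1.14 (1.45, adjusted p = 0.095, 0.94 with bounded members at their bounds). The list was called with slide in the fit (adjusted p = 0.018), with no filter on dim probes (0.045) and without wild type at 0 mM replicate 2 (0.034).

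At 0 mM limma called 5686 genes, 2798 higher and 2888 lower, 989 of them at least 2-fold. The fit with slide called 244 genes, 198 of them in the same direction as without it. The median standard error of a gene rose from 0.09 to 0.18 there, and 5629 of the 5686 genes kept their sign. Under E1A scaling 16598 genes were called, 95.7% higher, against 49.2%. Without SvGRP at 0 mM replicate 1, 2 or 3 the counts were 3229, 3125 and 3451, and without wild type at 0 mM replicate 3 it was 3593. Of the 72 named genes called, 42 were followed with 1 array left out. Of these 42, 6 lost the call without at least 1 array, each here with its highest adjusted p: PDF1.2 (adjusted p = 0.12 without SvGRP at 0 mM replicate 1), CYP704B1 (0.096 without wild type at 0 mM replicate 3), and CYP79F1 (0.054 without wild type at 0 mM replicate 1). The others were HSP17.4 (0.071 without SvGRP at 0 mM replicate 3), GATL4 (0.058 without SvGRP at 0 mM replicate 2) and GH9B15 (0.055 without SvGRP at 0 mM replicate 2).

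SvGRP against wild type at 150 mM is the comparison named in the series' title. The genes that were lower in SvGRP included clock and RNA-binding genes that were lower without salt too. GRP7 fell by 1.32 ± 0.08 (adjusted p = 1.8e-05, -1.15 with slide in the fit, adjusted p = 0.024), GRP8 by 1.00 ± 0.12 (-0.75, adjusted p = 0.16). ELF4 fell by 2.04 ± 0.09 (-2.14) and LUX by 1.72 ± 0.11 (-1.65), and CCA1 rose by 0.94 ± 0.07 (0.79) and PRR9 by 0.83 ± 0.06 (0.85). Aliphatic glucosinolate genes fell in 13 of 14 cases, BCAT4 (AT3G19710) by 3.59 ± 0.24 (adjusted p = 2.5e-05, -3.28) and CYP79F1 (AT1G16410) by 3.72 ± 0.51 (-3.47, adjusted p = 0.17), with a median of -1.66 (-1.26, adjusted p = 1.7e-10, and adjusted p = 0.58 with an estimated correlation). The vegetative storage protein genes VSP2 (AT5G24770) and VSP1 (AT5G24780) fell by 3.49 ± 0.20 (-2.78) and 3.20 ± 0.22 (-2.42). QQS, a gene of starch metabolism found only in Arabidopsis, fell by 4.24 ± 0.17 (adjusted p = 1.5e-06, -4.82) and ZIP7 was at least 4.52-fold lower (fitted -5.35, -5.40).

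In the indole glucosinolate and myrosinase list 7 of 12 genes fell, TGG2 by 1.96 ± 0.08 (-1.78) and UGT74B1 by 0.93 (-0.87, adjusted p = 0.053 with slide in the fit), with a median of -0.41 (-0.30, -0.25 under E1A scaling, adjusted p = 0.0035, and adjusted p = 0.58 with an estimated correlation). The jasmonate list had 8 falls and no rise among 20 genes, with a median of -0.93 (-0.56, -0.83 with 1 member below the threshold in both groups set to 0, -0.49 without wild type at 150 mM replicate 1, adjusted p = 3.5e-04, and adjusted p = 0.58 with an estimated correlation). Clade A phosphatases rose in 6 of 9 cases, HAB1 by 0.81 ± 0.17 (0.90, not called with slide in the fit), with a median of 0.65 (0.96, 0.35 without SvGRP at 150 mM replicate 3, adjusted p = 0.0039, and adjusted p = 0.58 with an estimated correlation). The LEA and dehydrin list held 4 rises, RD29B by 1.87 ± 0.57 (adjusted p = 0.034, 3.14, adjusted p = 0.20) and EM6 by 0.99 ± 0.31 (1.04, adjusted p = 0.49, and 0.056 with no filter on dim probes), and 1 fall among 26 genes, or 1 and 1 adjusted over the list alone. Its median was 0.45 (0.84, 0.71 without SvGRP at 150 mM replicate 1 and 0.23 without replicate 3, adjusted p = 0.0045, and adjusted p = 0.64 with an estimated correlation). The ABA synthesis and catabolism list had 3 rises, CYP707A4 by 0.73 (0.92, adjusted p = 0.17 with slide in the fit), and 1 fall among 11 genes (7 and 1 adjusted over the list alone), with a median of 0.39 (0.52, adjusted p = 0.025, and adjusted p = 0.58 with an estimated correlation). That call ended under quantile normalization (adjusted p = 0.068) and median scaling (0.051). P5CS1 rose by 0.82 ± 0.19 (1.29), ABF2 by 0.65 (0.75) and ABF3 by 0.51 (0.63), each called only without slide in the fit. RD29A had a change of 0.65 ± 0.23 (adjusted p = 0.062, 1.21), NCED3 of 0.80 ± 0.28 (adjusted p = 0.056, 1.12), HKT1 of 0.42, RAB18 of 0.18 and SOS1 of 0.05, none called. Under median and E1A scaling RD29A (adjusted p = 0.040 and 0.045), NCED3 (0.036 and 0.044) and HKT1 (0.043 and 0.020) were called, and HKT1 also under quantile normalization (0.66, 0.019). A fit with slide also called the lists of ABA kinases and transcription factors (median 0.48, adjusted p = 0.0020), heat shock (0.36, 0.017) and senescence (0.70, 0.0083).

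Root and root-hair markers fell in 7 of 13 cases, COBL9 by 2.48 ± 0.37 (-2.03) and PRX44 by 2.60 ± 0.43 (-1.85), neither called with slide in the fit. Their median was -0.69 (-0.50, adjusted p = 0.25 with slide in the fit, -0.51 with 1 member below the threshold in both groups set to 0, adjusted p = 0.043, and adjusted p = 0.64 with an estimated correlation). The root-hair expansin genes EXPA7 and EXPA18 fell by 2.64 ± 0.42 (-1.85) and 2.92 ± 0.52 (-1.57), again not called with slide in the fit, in a list with 10 falls among 22 genes (adjusted p = 0.079, against 0.027 under quantile normalization, 0.025 under median scaling and 0.0032 under E1A scaling). Cell division genes fell in 4 of 9 cases, the Aurora kinase gene AUR1 by 0.80 ± 0.07 (-0.88) and HINKEL by 0.73 (-0.84, adjusted p = 0.051 with slide in the fit). The median was -0.24 (-0.23, -0.083 under E1A scaling, -0.073 without wild type at 150 mM replicate 3, -0.11 without SvGRP at 150 mM replicate 3, adjusted p = 0.029, and adjusted p = 0.62 with an estimated correlation). The tonoplast aquaporin gene GAMMA-TIP fell by 1.06 ± 0.07 (-1.08), HAK5 by 2.75 (-2.59, adjusted p = 0.064 with slide in the fit) and the beta-amylase family gene BAM6 by 3.62 ± 0.21 (-3.40). JAL23 fell by 3.80 (-3.07, not called with slide in the fit), although another probe listed for it had a change of 4.72. The seed storage and oil body markers rose in 4 of 7 cases, CRA1 by 2.44 ± 0.37 (2.23) and OLEO2 by 2.196 ± 0.34 (1.85), neither called with slide in the fit, and fell in 1. Their median was 1.17 (0.95, 0.75 with 1 member at its bound, adjusted p = 0.025, and adjusted p = 0.58 with an estimated correlation). That call ended under quantile normalization (adjusted p = 0.053) and median scaling (0.078). The albumin gene SESA5 was at least 1.57-fold higher (fitted 3.14, 3.71).

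At 150 mM 7747 genes were called, 2746 higher and 5001 lower, 1208 of them at least 2-fold (233 higher, 975 lower). The share higher was 35.4%, against 50.1% under quantile normalization, 53.5% under median scaling and 65.6% under E1A scaling. With slide in the fit 239 genes were called, 34 higher and 205 lower, and 229 of them were called in the same direction without it. Without wild type at 150 mM replicate 2 the count was 5179. The list calls of ABA synthesis (adjusted p = 0.11 and 0.077), LEA and dehydrins (0.098 and 0.065) and cell division (0.14 and 0.15) ended without SvGRP at 150 mM replicate 3 and without wild type at 150 mM replicate 3. That of the root markers ended without any 1 of 5 arrays (highest 0.074, without wild type at 150 mM replicate 3). The gene calls that ended, each with its highest adjusted p, were RD29B (0.11 without wild type at 150 mM replicate 3), EM6 (0.12, the same array), AHG1 (0.094 without SvGRP at 150 mM replicate 3) and AO4 (0.051 without SvGRP at 150 mM replicate 2). Between the NaCl levels, 947 genes were higher in SvGRP at both (286.8 expected for independent lists), 1439 were lower at both (539 expected) and 168 went opposite ways. These counts were 11, 47 and 0 with slide in the fit. They were 3128, 322 and 440 under E1A scaling. With slide as a random block they were 2027, 2394 and 914, and with the replicate number as a block 625, 1119 and 98. Leaving out 1 array gave 494 (without SvGRP at 0 mM replicate 2) to 1050 (without SvGRP at 150 mM replicate 1) higher at both. It gave 960 (without SvGRP at 0 mM replicate 3) to 1540 (without SvGRP at 150 mM replicate 1) lower at both. The opposite ones then numbered 65 (without SvGRP at 0 mM replicate 2) to 476 (without wild type at 150 mM replicate 1).

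The interaction asked whether salt changed a gene differently in SvGRP, and a positive value is a higher response in SvGRP. RD29A was called, with 1.22 ± 0.33 (adjusted p = 0.049, 1.31 with slide in the fit, adjusted p = 0.29). It was not called under quantile normalization (adjusted p = 0.057), E1A scaling (0.090) or with no filter on dim probes (0.069). RD29B had 2.22 ± 0.80 (adjusted p = 0.11), P5CS1 0.72 ± 0.26 (adjusted p = 0.11), NCED3 0.63, RAB18 0.24, SOS1 0.15, HKT1 -0.07, GRP7 0.26 and GRP8 0.07, none called. WRKY70 had 2.64 ± 0.16 (adjusted p = 3.2e-04, 2.69): with salt it fell by 2.33 in wild type and rose by 0.31 in SvGRP. The ethylene synthesis gene ACS6 had 1.67 ± 0.16 (adjusted p = 0.0016, 1.802), the transcription factor gene ZAT10 2.02 ± 0.35 (2.21, not called with slide in the fit) and HSP70 1.37 ± 0.23 (1.51, likewise). Negative values came from GAMMA-TIP (-0.83 ± 0.10, -0.97), LDOX (-1.68 ± 0.24, -1.90), AUR1 (-0.73 ± 0.10, -0.66, not called with slide in the fit) and COBL9 (-2.89 ± 0.52, -2.32, likewise).

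The LEA and dehydrin list had a median interaction of 0.84 (0.90 with slide in the fit, adjusted p = 5.1e-09), with 5 of 26 genes called higher and none lower, COR15A at 1.40 ± 0.31 (1.23) and LTP4 at 3.83 ± 0.96 (5.05) among them. Neither was called with slide in the fit (adjusted p = 0.31 and 0.11), and LTP4 was not with no filter on dim probes (0.054). The heat shock list had 0.55 (0.87, 0.35 under E1A scaling, adjusted p = 9.6e-05, 3 of 19 higher, HSFA2 at 1.47, and 2.01 and not called with slide in the fit), and the clade A phosphatases 0.90 (0.83, 0.59 without SvGRP at 150 mM replicate 3, adjusted p = 0.0024, 0 of 9 called, and 2 higher adjusted over the list alone). Aliphatic glucosinolate genes had -0.75 (-0.73, adjusted p = 1.5e-04), with 6 of 14 called lower, BCAT4 at -1.68 ± 0.34 (-1.79) and MAM1 at -1.59 ± 0.42 (-1.55). Both lost the call with slide in the fit (adjusted p = 0.20 and 0.39), and MAM1 lost it also under median scaling (0.053) and with no filter on dim probes (0.067). Expansins had -0.45 (-0.50, adjusted p = 0.014, 5 of 22 lower, 1 higher), the root and root-hair markers -0.61 (-0.36, adjusted p = 0.18 with slide in the fit, -0.94 without wild type at 0 mM replicate 3, adjusted p = 0.014, 4 of 13 lower) and cell division genes -0.27 (-0.13, adjusted p = 0.0070, 4 of 9 lower, CYCB1-2 at -0.72, and -0.69 and not called with slide in the fit). The cell division median was -0.10 without wild type at 150 mM replicate 3, -0.14 without SvGRP at 150 mM replicate 3 and -0.47 under E1A scaling. Photosynthesis genes had 0.21 (0.18, adjusted p = 3.8e-07, 1 of 34 called, and 0 adjusted over the list alone, 0.01 under E1A scaling, and 0.12 without SvGRP at 150 mM replicate 1). Their call ended under quantile normalization (-0.01, adjusted p = 0.83). The jasmonate list was called with slide in the fit (-0.80, adjusted p = 1.8e-05) and without wild type at 150 mM replicate 3 (-0.69, adjusted p = 0.039). With an estimated correlation each of the 15 lists called here had an adjusted p of 0.58. The call of the expansins ended without SvGRP at 150 mM replicate 3 (adjusted p = 0.054) and that of the root markers without wild type at 0 mM replicate 2 (0.053). Gene calls ended too, each here with its highest adjusted p: COR15A (0.065) and BCAT4 (0.056) without SvGRP at 0 mM replicate 1, HSFA2 (0.071) without the same array, LTP4 (0.081) without wild type at 150 mM replicate 2 and MAM1 (0.11) without SvGRP at 0 mM replicate 2.

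**Figure D3:**
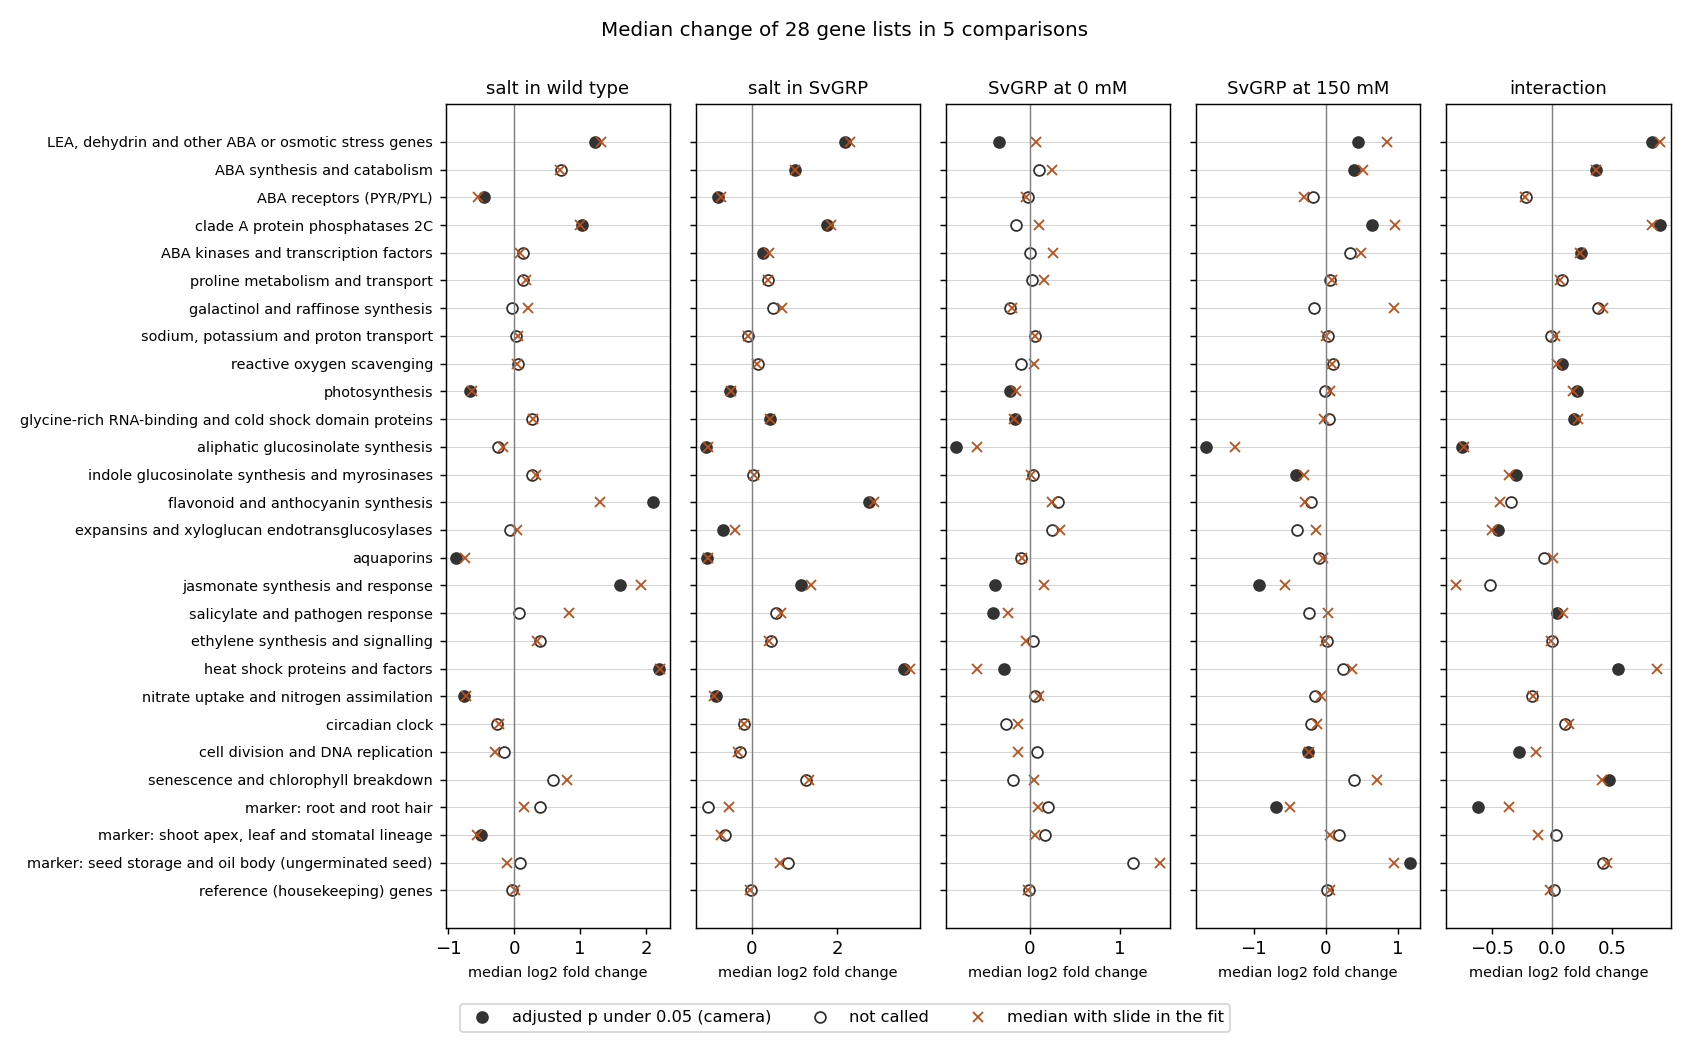
Median log2 fold change of the 28 gene lists in the 5 comparisons (circles, filled where camera's adjusted p was under 0.05) and the same median with slide in the fit (crosses). Aliphatic glucosinolate genes lie lowest at 150 mM, at -1.66, and the LEA and dehydrin list lies at 0.84 in the interaction; scalings that turn the median of a list called by camera are given in the text.

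For the interaction 2402 genes were called, 675 higher and 1727 lower, 880 of them at least 2-fold. The share higher was 28.1%, against 44.5% under quantile normalization, 46.2% under median scaling and 6.40% under E1A scaling. The fit with slide called 138, 53 higher and 85 lower, and 100 of them were called in the same direction without it. The count fell to 851 without SvGRP at 0 mM replicate 1, 996 without replicate 2 of that group and 987 without wild type at 150 mM replicate 2. It was 1376 and 1422 without wild type at 0 mM replicates 2 and 3, and 1472 without SvGRP at 150 mM replicate 2, and it was 3655 without SvGRP at 150 mM replicate 1. Of the 51 named genes called, 42 were followed with 1 array left out. Of these 42, 21 lost the call without at least 1 array, RD29A among them (highest adjusted p 0.11, without wild type at 150 mM replicate 2).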

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

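The regroupings and the tests of explanations in this part were chosen only after the result was seen. What follows was singled out because the response to salt differed between the genotypes by the test of the interaction, which called 2402 genes. Among 100 regroupings of the residuals, real grouping included, 1 called as many genes, and the highest of the others called 250. The residuals still hold the interaction, so a real one widens the spread in the other regroupings and lowers their counts. The value of 250 thus gives no level for chance, and the rank speaks against chance only for arrays that are exchangeable. The regroupings leave the slides out and so say nothing of a slide difference, and with slide in the fit 138 genes were called.

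List medians of the interaction were 0.84 for LEA and dehydrin genes, 0.36 for ABA synthesis and catabolism, 0.90 for clade A phosphatases, 0.24 for ABA kinases and transcription factors, 0.08 for reactive oxygen scavenging (-0.12 under E1A scaling), 0.21 for photosynthesis (-0.01 under quantile normalization), 0.19 for glycine-rich RNA-binding proteins (-0.01 under E1A scaling) and 0.55 for heat shock genes. They were -0.75 for aliphatic and -0.30 for indole glucosinolates, -0.45 for expansins, -0.27 for cell division, 0.48 for senescence, -0.61 for the root and root-hair markers, and 0.045 for the salicylate list (-0.15 under E1A scaling), whose mean was 0.42. With an estimated correlation each of these 15 lists had an adjusted p of 0.58. Under E1A scaling medians moved over 1.5 times to 0.16 for ABA synthesis, 0.040 for ABA kinases, 0.010 for photosynthesis, 0.35 for heat shock, -0.50 for indole glucosinolates, -0.47 for cell division and 0.28 for senescence. ABA synthesis was at 0.57 and the salicylate list at 0.28 under quantile normalization. Median scaling put reactive oxygen scavenging at 0.15 and the salicylate list at 0.11. A fit with slide ended 5 calls: ABA synthesis (0.36, adjusted p = 0.062), reactive oxygen scavenging (0.038, 0.28), the salicylate list (0.092, 0.18), senescence (0.42, 0.071) and the root markers (-0.36, 0.18). The other medians were then 0.90 for LEA and dehydrin genes, 0.83 for clade A phosphatases, 0.23 for ABA kinases, 0.18 for photosynthesis, 0.21 for glycine-rich proteins, 0.87 for heat shock, -0.73 and -0.36 for aliphatic and indole glucosinolates, -0.50 for expansins and -0.13 for cell division. Calls also ended with no filter on dim probes for ABA synthesis (adjusted p = 0.078), reactive oxygen scavenging (0.092) and the salicylate list (0.071). They ended under quantile normalization for reactive oxygen scavenging (0.37) and photosynthesis (0.83), and under median scaling for ABA synthesis (0.070) and the salicylate list (0.090). Calls ended without any 1 of 3 arrays for ABA synthesis (highest adjusted p = 0.11, without SvGRP at 150 mM replicate 3) and of 6 for indole glucosinolates (0.13, without SvGRP at 150 mM replicate 2). They ended without 1 array for expansins (0.054 without SvGRP at 150 mM replicate 3), the root markers (0.053 without wild type at 0 mM replicate 2), and senescence (0.061 without wild type at 150 mM replicate 3). Those of reactive oxygen scavenging (0.090 and 0.055) and the salicylate list (0.11 and 0.052) ended without wild type at 150 mM replicate 3 and without SvGRP at 150 mM replicate 3.

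Leaving out 1 array moved some of these medians by over 1.5 times. Without SvGRP at 150 mM replicate 1 they were 0.59 for ABA synthesis, 0.12 for photosynthesis and 0.76 for senescence. Without replicate 3 of that group they were 0.59 for clade A phosphatases, -0.14 for cell division and 0.32 for senescence. Without wild type at 150 mM replicate 3 they were -0.10 for cell division and 0.27 for senescence. Senescence was also at 0.29 without wild type at 0 mM replicate 3 and 0.28 without SvGRP at 0 mM replicate 3, and the root markers were at -0.94 without wild type at 0 mM replicate 3. Reactive oxygen scavenging was at 0.13 without wild type at 0 mM replicate 1 or SvGRP at 150 mM replicate 2. The salicylate median ran from 0.0007 (without wild type at 150 mM replicate 3) to 0.32 (without wild type at 150 mM replicate 1).

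The highest fitted gene values were 6.10 for CYP93D1, 5.92 for ANK, 5.62 for PCC1, 3.90 for ERF13, 3.86 for CYP76G1, 3.83 for LTP4, 3.60 for CYP712A2 and 3.57 for TRFL2. CYP93D1, ANK, CYP76G1 and CYP712A2 were above the dim-probe threshold only in wild type at 0 mM, so that their fitted values are no measure of size. The largest negative ones were -3.58 for RHS18, -3.32 for TET12, -3.30 for RSH4, -3.26 for AGP3, -3.24 for PRP3, -3.18 for MYB113, -3.06 for MES15 and -3.05 for MRH6, and RD29A had 1.22. With slide in the fit CYP93D1, CYP76G1 and CYP712A2 of these were called, and the other 14 were not. Calls ended under quantile normalization for RHS18, PRP3, MYB113 and RD29A, under E1A scaling for RD29A, and with no filter on dim probes for LTP4, RHS18, AGP3, PRP3, MRH6 and RD29A, with an adjusted p of at most 0.090. The calls of PCC1, LTP4, RHS18, TET12, RSH4, AGP3, PRP3, MYB113, MRH6 and RD29A ended without at least 1 array. The highest adjusted p was 0.070 for PCC1, 0.061 for TET12, 0.053 for RSH4, 0.11 for RHS18, 0.10 for AGP3, 0.11 for PRP3, 0.081 for MYB113 and 0.097 for MRH6 (without SvGRP at 0 mM replicate 1 or 2), and 0.081 for LTP4 and 0.11 for RD29A (without wild type at 150 mM replicate 2).

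LEA and dehydrin genes responded more to salt in SvGRP, with a mean interaction of 1.01 (95% interval 0.12 to 1.90, and 0.81 or -0.23 to 1.85 under E1A scaling). Their mean in SvGRP against wild type was -0.49 at 0 mM (-1.12 to 0.15) and 0.52 at 150 mM (-0.11 to 1.15). With slide in the fit it was -0.08 (-1.39 to 1.23) and 1.03 (-0.28 to 2.34). Each of these intervals holds 0, so a higher level under salt is not shown, and a lower level at 0 mM may enter the interaction. The list's interaction lay above that of all other genes by 1.13 (0.25 to 2.00). This argues against the scaling, since an array-wide factor moves every gene alike. A response larger by 1 factor in all salt-regulated genes was also tested. The 144 members of the 9 other lists called for salt in wild type lay at -0.74 from the value needed (-1.29 to -0.20). Photosynthesis genes, 1 of these lists, lay at -0.58 alone (-0.90 to -0.25). Both values argue against it, but the lists were chosen by the wild-type response. That response also enters the distance, which can push it below 0. Under E1A scaling both intervals hold 0 (-0.96 to 0.06 and -0.37 to 0.18), as does that of photosynthesis under quantile normalization (-0.22 to 0.01), and the 4366 genes with an average salt response of at least 2-fold responded more by 0.30 (0.02 to 0.58) where 0.93 was needed, a distance whose interval holds 0 too (-1.39 to 0.14), so it stays open. With slide in the fit the list's mean interaction was no smaller, 1.11. Camera called the list there at its preset correlation (adjusted p = 1.1e-07, while the call without slide has 0.58 with an estimated correlation). The interval of the mean interaction holds 0 (-0.29 to 2.51), so a slide difference stays open. A stronger ABA response in the transformant may also account for the pattern and cannot be told apart from these 2 here.

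Root-hair genes were lower in SvGRP than in wild type at 150 mM, by a mean of -1.95 (-2.73 to -1.17). The other root markers had -0.24 (-0.75 to 0.27), and the root-hair markers lay below them by -1.71 (-2.26 to -1.17). A lower share of root tissue alone would lower both alike, so this argues against it as the whole cause. The sets do not always move together, though. Salt in wild type changed the root-hair markers by 0.75 (-0.02 to 1.53) and the others by -0.90 (-1.42 to -0.39). Whether root share plays a part thus stays open. With slide in the fit the mean of the root-hair markers was -1.34 (-2.88 to 0.20), so a slide difference stays open. A difference in root-hair development under salt may account for it and was not tested.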

How the results depend on the processing

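The median and E1A scalings were chosen after seeing the data. Of 6547 genes with several tested probes, a second probe was called the opposite way in 120, 137, 37, 27 and 0 genes in the order of the report. At least 2-fold changes numbered 3985, 5367, 989, 1208 and 880. With slide as a fixed block the genotype comparisons gave 244 (0 mM) and 239 (150 mM) genes, the interaction 138, and 224 of 409 named-gene results were called; with slide as a random block they gave 10264, 11979 and 7384. The fixed block costs precision and the random block assumes slides unrelated to the groups. The random block had a consensus correlation of -0.16. A negative value is no slide variance and narrows the errors of contrasts between slides. The higher counts with the random block are thus no sign of more differences. Which part of the change with the fixed block is a slide effect was not tested. E1A scaling gave 16598 genes at 0 mM, a fit of only the groups compared 3757 at 150 mM, and an estimated correlation left 0 of 55 list calls; the cause was not tested. Directions turned for GRP7 and GRP8 for salt in wild type under quantile normalization (0.17 and 0.083) and E1A scaling (0.11 and 0.024), for the photosynthesis list at 0 mM under quantile normalization (0.034) and for the jasmonate list at 0 mM with slide as a fixed block (0.16); the cause was not tested. Medians of other called lists changed sign at 0 mM with slide as a fixed block (LEA 0.064) and under E1A scaling (LEA 0.022, photosynthesis 0.14, heat shock 0.068, glycine-rich 0.20), and for the interaction under E1A scaling (reactive oxygen -0.12, salicylate -0.15, glycine-rich -0.012) and quantile normalization (photosynthesis -0.0069). Leaving out 1 array gave 3125 (without SvGRP at 0 mM replicate 2) to 6825 (without SvGRP at 150 mM replicate 1) genes at 0 mM and 851 (without SvGRP at 0 mM replicate 1) to 3655 (without SvGRP at 150 mM replicate 1) for the interaction. Replicate numbers do not pair the arrays: residuals of 18 same-number pairs correlated at -0.18 to 0.22 (median -0.07), and 2 of 12 arrays had their best partner under their own number; with the number as a block the interaction gave 1215 genes. Other totals of genes called per comparison, of list calls, of named-gene calls and of genes called the same way in both salt responses stayed within 1.5 times. Genes called opposite ways in both numbered 280, 67 with slide as a fixed block, 706 as a random block and 159 to 615 without 1 array. The series table is the same values rescaled, so it tests nothing further, and the background correction with normexp was not run. Signals near the floor, which was higher on slide 1 (lowest signal 5.15 to 6.25, against 1.63 to 2.21 on the other slides), limit what can be measured for dim genes. The highest signal was 579476 to 625724 on all arrays, which may limit bright genes. In wild type at 0 mM GRP7 lay 6.81 to 7.12 (log2) above the 75th percentile and the mean of the photosynthesis list 6.23 to 6.39. Whether such probes were saturated was not tested.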

Other observations

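The test of clock genes outside the list was written before its result was seen; the other tests here were chosen only after. Clock genes outside the fixed list showed the genotype difference too. PRR3 and COR28, which peak in the evening, fell by 2.77 and 3.47 in SvGRP at 0 mM and by 2.15 and 2.06 at 150 mM. Of 9 morning genes measured, 4 were called higher at both NaCl levels in SvGRP, LNK1 (0.21 and 0.53), LNK2 (0.51 and 0.57), CDF1 (0.46 and 0.70) and CDF3 (0.49 and 0.56), none of which was called with slide in the fit. RVE2 fell by 1.03 at 0 mM (not called with slide in the fit) and had -0.39 at 150 mM (adjusted p = 0.093). From the fixed list, a set of evening genes (TOC1, LUX, ELF4 and ELF3) averaged -1.34 at 0 mM and -1.40 at 150 mM. A set of morning genes (CCA1, LHY, PRR9 and RVE1) averaged 0.53 and 0.64, and the list's other members entered neither set. The whole list of 12, which mixes both phases, was not called, with 3 rises and 6 falls at 0 mM (adjusted p = 0.088, but 0.0010 under E1A scaling and 0.047 without wild type at 0 mM replicate 1) and 5 and 5 at 150 mM (adjusted p = 0.62).

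Time-of-day genes thus differed between the genotypes at both NaCl levels. With slide in the fit evening minus morning genes of the fixed list was -1.72 at 0 mM (95% interval -2.11 to -1.33). At 150 mM it was -1.92 (-2.31 to -1.54). For the genes of these sets, this argues against the slides as the whole cause. The test was chosen after the difference was seen and leaves out the list's other members, so it says nothing of the whole list. In the genes outside the list, evening minus morning was -3.31 (-3.55 to -3.07) and -2.46 (-2.70 to -2.22) without slide in the fit. These values rest mainly on 2 evening genes, PRR3 and COR28, which averaged -3.12 and -2.10. The 9 morning genes averaged 0.19 and 0.35. With slide in the fit the morning mean was 0.13 at 0 mM (-0.06 to 0.32) and 0.28 at 150 mM (0.08 to 0.47). The difference between evening and morning genes goes with a different time-of-day state of the SvGRP samples. Its sign alone cannot tell an earlier from a later one. Such a state may come from the harvest hour, not given in the labels, or from the genotype. GRP7 and GRP8 minus the evening genes was 0.016 at 0 mM (-0.12 to 0.15) and 0.24 at 150 mM (0.10 to 0.37), and since genes differ in amplitude this leaves open whether the transgene lowers them by a route of its own.

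Of the 10 splits of 6 arrays into 3 and 3, which are too few for a share under 0.05, the real split called 16278 genes for salt in wild type, 17867 for salt in SvGRP, 7608 for SvGRP at 0 mM and 3757 at 150 mM in a fit of those arrays alone, and 1 split, the real one, called as many in each case. The highest of the other splits called 0 genes in limma, with at most 580, 365, 883 and 2188 genes at an unadjusted p under 0.05. Each of the other splits mixes the compared groups, so a real difference widens the spread on both sides. A count near 0 was thus fixed beforehand and gives no level for chance.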
